A study of Mus musculus with 20 samples.

How the data were processed

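Polyadenylated RNA was sequenced from 2 sorted populations of cultured mouse bone marrow cells, HSC and HPC, each wild type (WT), heterozygous (het) or homozygous (hom) for a Runx2 knockout, in 3 libraries per group (18 libraries). The design text of the series speaks of conditional deletion or of CRISPR knockout, and the labels do not say which was used for a given library. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trim Galore 0.6.10, aligned with STAR 2.7.11a and counted with featureCounts 2.0.6. The deposited values are raw gene counts, 1 table per cell type with 49997 genes each, made per the file headers by featureCounts 2.0.6 from paired reads without regard to strand, over exons summed by gene. The processing notes name the mm39 build and the file headers an mm10 annotation. The coordinates in the tables are those of mm10 and are given as such. The CUT&Tag samples of the series were not analysed here.

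Samples, comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The main fit was the edgeR 4.0.16 quasi-likelihood F test (robust) in R 4.3.3, with TMM factors, genes kept by filterByExpr on the groups, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and only called genes are said to have risen or fallen. One fit of 9 libraries per cell type gave hom against WT, het against WT, hom against het and any difference across genotypes. One fit of all 18 libraries, with the 2 tables joined by gene, gave the difference in the hom effect between HSC and HPC and the comparison of WT HSC with WT HPC. CPM (counts scaled to library size) were computed here from the counts and the TMM factors of the fit, so a gene's CPM can differ slightly between the fits. The CPM of Ddx3y and Xist, and those under other observations, use all counts without TMM factors. Values after ± are the SD of 3 libraries for CPM and the standard error of the fit for log2 fold changes.

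The libraries held 18471641 to 23417608 counts in HSC WT, 20270575 to 27061457 in HSC het and 18050298 to 21728340 in HSC hom. They held 21386411 to 22284511 in HPC WT, 16663497 to 20633138 in HPC het and 19060670 to 21058030 in HPC hom. A level of 3 counts, the lowest at which 0 counts are unlikely by counting error alone, equals 0.111 to 0.18 CPM, and this floor covers counting error only. No fold change is given against a group at 0 counts, except that the fitted difference of Fcer1a in the hom effect is printed, and some list means and counts take in members at 0 counts in a group. These values are no bounds. The labels do not say whether replicates are separate animals, cultures or preparations. The p-values therefore measure the spread between libraries, which may be technical. No 2 libraries of a group were duplicates.

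Gene lists, 32 with 649 entries of which 646 were found, were written from general knowledge of lineage markers, cell cycle, signalling, stress and metabolism. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01. The same test with an estimated correlation and the rotation test fry, which asks whether genes move on balance one way, were run beside it. Adjustment was over the lists of a comparison. Runx2 was left out of list tests. Across the 8 comparisons 84 list calls were made with the preset correlation and 5 with an estimated one, and fry kept 50 of the 84.

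Named genes are the RUNX genes and Cbfb; for hom against WT the 8 higher and 8 lower called genes with the largest change, and for other comparisons 4 and 4, among those whose groups did not overlap and whose higher group had a mean of at least 5 CPM, without predicted genes; up to 4 called members of each list described, by p; and the sort markers Procr, Slamf1, Kit and Ly6a. A few genes that the rule selects are not reported here. For 3 libraries against 3, values fail to overlap by chance for 10% of genes. Genes outside this rule are said to be chosen after their values were seen where a count was small, and otherwise are members of a list or of the genes shared by both cell types. Reads in exons shared by overlapping genes are not counted for either gene, and copies on alternate contigs can lower a gene's counts. This concerns Runx3, Mpo, Cd28, Lck, H2-Aa, H2-Ab1, H2-DMa, H2-Eb1, Sgms2, Dscam and Xlr3b (alternate contigs) and Ccna2, Nusap1, Ifi27, Ifi27l2a, Igsf10, Yes1, Cd7, Usp18, Cox6a2, Sgms2 and Xist (over 5% of exons overlapping), whose levels are uncertain.

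Overlaps of calls were tested with Fisher's exact test against the product of the 2 call shares. Comparisons that share WT libraries were set beside 20 simulated draws of unchanged groups and beside fits with separate WT libraries for het and hom. The alternatives tried were DESeq2 1.42.0, RLE size factors, no filter on low counts, at least 1 CPM in 3 libraries, limma-voom, a block for the replicate number, only the groups compared in the fit, and each library left out in turn. A run without X- and Y-linked genes was added after the sex of the libraries was seen. The pipeline was tested on simulated data with 200 changed genes per comparison. For hom against WT edgeR found 52% of 1.5-fold, 68% of 2-fold and 94% of 3-fold changes in HSC, with 6.63% of its calls false, and 72%, 84% and 94% in HPC, with 5.43% false. DESeq2 had 14.7% false calls in HSC. The simulated genes were drawn independently, so these rates leave out genes that move together within a library.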

Results

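RNA was sequenced from cultured blood-forming cells of mouse bone marrow that differed in the gene Runx2, which encodes a transcription factor of the RUNX family. One population, called HSC here, was sorted as positive for CD201, CD150, Kit and Sca1 and negative for lineage markers, the surface phenotype of haematopoietic stem cells. The other, called HPC here, was Kit-positive, Sca1-positive and lineage-negative but lacked CD201 and CD150, the phenotype of progenitors. Cells of each kind were wild type (WT), heterozygous (het) or homozygous (hom) for a Runx2 knockout, which gave 6 groups of 3 libraries. The series presents Runx2 as a regulator of stem cell expansion and of commitment to the T-cell lineage, and the comparisons ask which transcripts moved with the genotype in each population. The 18 libraries held between 16663497 and 27061457 counts assigned to genes, and mitochondrial genes took 1.46% to 2.59% of them. All 9 HSC libraries contained transcripts of the Y-linked gene Ddx3y (121 to 167 CPM, counts scaled to library size). All 9 HPC libraries had 0 counts of it and 2539 to 4475 CPM of Xist, the RNA of the inactive X chromosome. Cell type and donor sex therefore went together, while the genotypes of a cell type shared one sex.

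Runx2 counts followed the genotype labels in every library. In HSC, Runx2 (chromosome 17, 44495987 to 44814797, mm10) stood at 130 ± 3.51 CPM in WT, 91.2 ± 4.35 in het and 28.2 ± 1.93 in hom (SD, n = 3). Hom cells thus kept 21.7% of the WT level, a log2 fold change of -2.20 ± 0.08 (SE; edgeR adjusted p = 7.54e-10), and het cells kept 70.1% (log2 -0.51 ± 0.07, adjusted p = 0.0167). In HPC the means were 117 ± 4.40, 97.0 ± 4.38 and 21.9 ± 1.09 CPM. Hom cells there kept 18.7% (log2 -2.42 ± 0.07, adjusted p = 4.25e-14) and het cells 82.7% (log2 -0.27 ± 0.06, adjusted p = 0.00392). Gene counts also take in exons outside a deleted part, and which exons were removed is not given in the sources used here. The heterozygous call in HSC rested on nearly all libraries. Without any 1 of WT replicates 1, 2 and 3 and het replicates 1 and 3 the adjusted p lay between 0.0687 and 0.17, with the fold change nearly unmoved at -0.53 to -0.49.

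**Figure D1:**
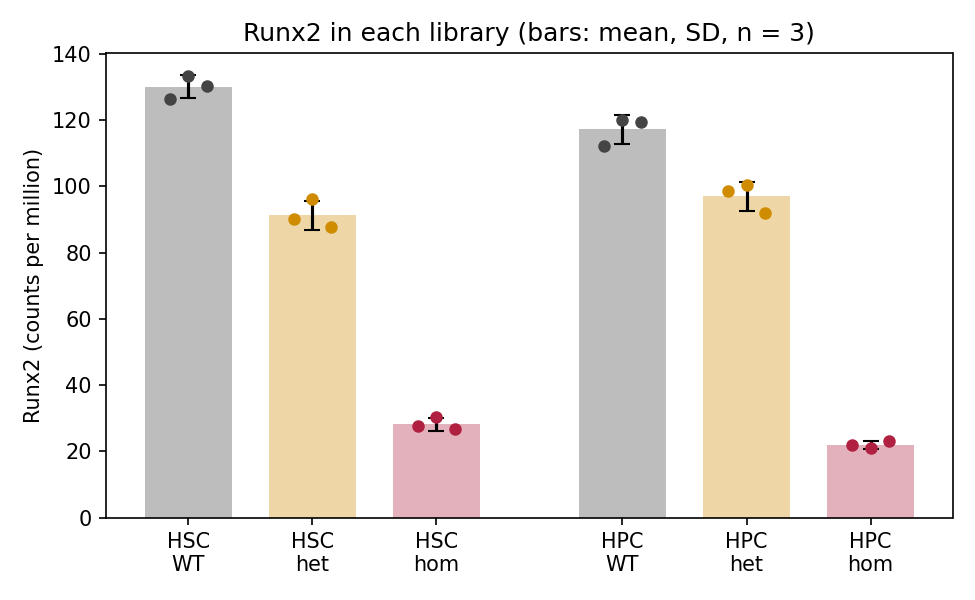
Runx2 in CPM (vertical axis) in the 3 libraries of each of the 6 groups, with bars for the mean and error bars for the SD (n = 3). Hom libraries lie at 26.7 to 30.4 CPM in HSC and 20.9 to 23.0 CPM in HPC, below every het and WT library of the same cell type.

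The other RUNX genes moved little. In HPC hom, Runx1, a central transcription factor of blood formation, rose to 122% of WT (log2 0.29 ± 0.06, edgeR adjusted p = 0.00421) and Runx3, which acts in T cells, fell to 83.4% (log2 -0.26 ± 0.08, adjusted p = 0.0406). In HSC hom the same genes had log2 changes of 0.16 ± 0.07 and 0.14 ± 0.06, which did not pass (adjusted p = 0.242 and 0.243). Cbfb, the shared partner of RUNX proteins, passed in neither cell type (log2 -0.11 ± 0.07 in HSC, 0.07 ± 0.06 in HPC). Runx3 has an annotated second copy on an alternate contig, and its call in HPC was lost in 4 of the 6 fits that left out 1 library.

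In HSC hom, Il18r1, Lpl and Ccl22 were among the genes that fell relative to WT, and Tlr7 and Ifi209 among those that rose. Il18r1, a chain of the interleukin-18 receptor (chromosome 1, 40465552 to 40500854), fell from 10.7 ± 1.85 to 2.79 ± 0.37 CPM (SD, n = 3; log2 -1.94 ± 0.20, edgeR adjusted p = 0.000725). Lpl, lipoprotein lipase, fell from 7.71 ± 1.17 to 1.94 ± 0.41 CPM (log2 -1.99 ± 0.24, adjusted p = 0.00185), and the chemokine gene Ccl22 from 6.75 ± 1.64 to 2.21 ± 0.65 CPM (log2 -1.61 ± 0.31). Tlr7, a receptor for single-stranded RNA, rose by log2 1.14 ± 0.20 and the interferon-inducible Ifi209 by 2.02 ± 0.34.

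Of 14959 genes tested in HSC, 180 were higher and 120 lower in hom than in WT. The largest rises by the rule for named genes also took in Rgs8 (log2 1.92 ± 0.26), Gimap3, a GTPase of lymphocytes (1.77 ± 0.29), the monoamine transporter Slc18a1 (1.42 ± 0.25), the germline helicase Ddx4 (1.34 ± 0.25) and Siglecg, an inhibitory receptor of B cells (1.17 ± 0.16). The largest falls also took in Serpinh1, a chaperone of collagen (-1.43 ± 0.25), Serpinf1 (-1.41 ± 0.26), the ciliary gene Evc (-1.40 ± 0.27) and Igsf10 (-1.39 ± 0.27), 16.6% of whose exons overlap Med12l. For each of these genes all 3 hom libraries lay on one side of all 3 WT libraries. Transcripts of the sort markers did not pass the test: Procr (CD201) had a log2 change of 0.15 ± 0.17, Slamf1 (CD150) -0.14 ± 0.12 and Kit 0.14 ± 0.08. The count of 300 genes was unstable, at 810 with DESeq2, 898 without a filter on low counts and 155 with only these 2 groups in the fit. Without WT replicate 1, 2 or 3 it was 76, 48 or 92, and without hom replicate 1, 2 or 3 it was 592, 71 or 638.

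Among the fixed gene lists, G2 and mitosis genes were called lower and interferon-response genes higher in HSC hom, but not with an estimated correlation. Of 25 tested genes of G2 and mitosis, 5 fell, none rose and 20 did not pass (13 fell adjusted over the list alone). Cyclin B1 (Ccnb1) fell by 0.46 ± 0.07 on the log2 scale, the spindle gene Nusap1 by 0.41 ± 0.07 and cyclin A2 (Ccna2) by 0.36 ± 0.06. The list mean was -0.25, -0.23 and -0.22 relative to WT in the 3 hom libraries (camera adjusted p = 1.76e-10; adjusted p = 0.0867 with an estimated correlation). Of 25 interferon-response genes, 8 rose, none fell and 17 did not pass (16 rose adjusted over the list alone). Ifi27l2a rose by 1.10 ± 0.15, Irf7, a transcription factor of the interferon response, by 0.85 ± 0.12, and the antiviral enzymes Oas2 and Oas3 by 0.68 ± 0.11 and 0.50 ± 0.10 (camera adjusted p = 8.03e-09; adjusted p = 0.744 with an estimated correlation and 0.132 with fry). The interferon list mean was 0.37, 0.27 and 0.55 in the hom libraries, and 0.35 in het replicate 2 against -0.04 and 0.09 in the other het libraries. None of 18 immediate early and handling-stress genes passed, and the list as a whole was called lower (camera adjusted p = 0.0092; adjusted p = 0.744 with an estimated correlation, 0.293 with fry and 0.13 without WT replicate 2), with library means of -0.84, -0.64 and 0.01.

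T-cell genes were among those that fell in HSC hom. Of 16 tested T-cell commitment genes, 3 fell, none rose and 13 did not pass (4 fell and 1 rose adjusted over the list alone). These were Tox (log2 -1.25 ± 0.14, edgeR adjusted p = 0.00173) and Tcf7 (-0.92 ± 0.17, adjusted p = 0.0154), transcription factors of early T-cell development, and Thy1, a surface protein of T cells and stem cells (-0.75 ± 0.14, adjusted p = 0.0165). The list as a whole did not pass (camera adjusted p = 0.289), and its median log2 change of 0.02 had the opposite sign to the downward test. Of 18 progenitor and lymphoid-priming genes, 3 rose, among them Cd48 (log2 0.34 ± 0.08) and Flt3, a cytokine receptor of early lymphoid progenitors (0.32 ± 0.08). The chemokine receptor Ccr7 fell (-1.37 ± 0.28) and 14 did not pass (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.179). The integrin genes Itgb2, Itgb7 and Itga9 rose by 0.41 ± 0.07, 0.62 ± 0.12 and 0.80 ± 0.15, within an adhesion list of which 4 of 26 rose, 1 fell and 21 did not pass (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.768, upward, against a median of -0.03). None of 29 HSC identity genes passed (0 also adjusted over the list alone; camera adjusted p = 0.179), and their mean ran from -0.52 to 0.21 across the 3 hom libraries. Markers of neutrophil granules (0 of 11), mast cells (0 of 12) and megakaryocytes (0 of 20) had no member that passed. Of 13 monocyte genes, the chemokine receptor Ccr2 fell (-1.84 ± 0.30, adjusted p = 0.00796; 0.0634 without WT replicate 2) and 12 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.285). Of 14 dendritic cell genes, H2-Eb1 (-2.09 ± 0.41) and H2-Aa (-1.51 ± 0.35) fell, H2-DMa rose (0.42 ± 0.10) and 11 did not pass (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.85), and of 12 erythroid genes Hemgn fell (-0.42 ± 0.08) and 11 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.244). The calls of H2-Eb1, H2-Aa, H2-DMa and Hemgn were lost in 3, 5, 5 and 4 of the 6 fits that left out 1 library. These H2 genes lie on chromosome 17 within 20 Mb of Runx2.

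Few single genes were called in heterozygous HSC. The 5 were Runx2, which fell, and Commd10 (log2 0.93 ± 0.12, edgeR adjusted p = 0.00571), the interferon-inducible Ifi27 (0.62 ± 0.09, adjusted p = 0.0286), Sva and Gm32920, which rose. Sva and Gm32920, named because the count was small and after their values were seen, had 0 counts in all 3 WT libraries and 2.34 ± 0.70 and 1.64 ± 0.71 CPM in het (SD, n = 3). Between hom and het HSC, Runx2 (log2 -1.69 ± 0.08) and Gm4258 (0.94 ± 0.13, adjusted p = 0.04), the latter also named after the fact, were the 2 genes called. Of 14959 genes, 2067 had an unadjusted p under 0.05 and 3441 (23%) had het and WT libraries that did not overlap. By chance 10% of independent genes would do so, but genes of a library move together. Chance could not be tested with 3 libraries against 3. Hom and WT HSC libraries did not overlap for 24.5% of genes, and 300 were called. The fitted spread between libraries of a group was larger in HSC than in HPC (common dispersion 0.0128 and 0.00483). Equal changes were thus harder to call in HSC, so the counts of calls do not compare effect sizes between the cell types. As lists, S phase (camera adjusted p = 2e-06), G2 and mitosis (5.15e-06), MYC and ribosome biogenesis (5.15e-06), cholesterol synthesis (0.00318) and mitochondrially encoded genes (0.0216) were called lower and HSC identity (0.0322) and interferon-response genes (0.0368) higher in het than WT. No single member was called, and over the list alone 4, 8 and 4 members of the first 3 lists were lower, 3 interferon genes higher and none of the others changed. No list call held with an estimated correlation (adjusted p = 0.351 for G2 and mitosis and 0.966 for the others), and with fry only G2 and mitosis did (adjusted p = 0.0374). Without WT replicate 2 or het replicate 2 the adjusted p was 0.0605 or 0.091 for cholesterol synthesis, 0.163 or 0.392 for mitochondrially encoded and 0.0605 or 0.194 for HSC identity genes (0.161 without WT replicate 1), and without WT replicate 3 or het replicate 2 it was 0.454 or 0.979 for interferon genes. The interferon call was also lost with a block for the replicate number. Between hom and het HSC, 10 lists were called, 4 higher and 6 lower in hom. Among them HSC identity was lower (camera adjusted p = 2.48e-05) and S phase and MYC and ribosome biogenesis higher (0.000604 and 0.00312), against the het shifts above. None of the 10 held with an estimated correlation or with fry. DESeq2 called 216 genes for het against WT and 174 for hom against het, no filter gave 399 and 511, and a fit of only the 2 groups 299 and 1. Without WT replicate 1 or 2 or het replicate 1 or 3 the het count was 2, 3, 2 or 2, and for hom against het it was 1, 4 or 1 without het replicate 1, 2 or 3 and 8 or 408 without hom replicate 1 or 3.

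In HPC hom, genes of neutrophils and monocytes rose relative to WT, and H2-Aa, H2-Eb1 and Il18r1 were among the genes that fell. Ly6c2, a surface antigen of inflammatory monocytes (chromosome 15, 75108161 to 75112066), rose from 1.62 ± 0.26 to 15.1 ± 1.17 CPM (SD, n = 3; log2 3.22 ± 0.16, edgeR adjusted p = 4.19e-10), although reads shared with its close paralogs were not separated here. S100a9 and S100a8 (chromosome 3, 90692630 to 90695721 and 90669071 to 90670034), the subunits of the neutrophil protein calprotectin, rose by log2 2.27 ± 0.24 and 1.91 ± 0.28. F13a1, coagulation factor XIII of macrophages, rose from 16.4 ± 0.95 to 52.0 ± 3.25 CPM (log2 1.67 ± 0.09, adjusted p = 9.33e-10). H2-Aa and H2-Eb1 (chromosome 17, 34282744 to 34287823 and 34305867 to 34316674), chains of MHC class II, fell from 6.75 ± 0.10 and 7.05 ± 0.74 to 1.06 ± 0.44 and 1.09 ± 0.71 CPM (both log2 -2.67), with annotated second copies on alternate contigs. H2-Ab1, another class II chain chosen after its values were seen, did not pass (log2 0.03 ± 0.14, 16.9 CPM against 16.5). Il18r1 fell from 10.5 ± 0.44 to 2.01 ± 0.52 CPM (log2 -2.38 ± 0.17, adjusted p = 2.27e-08).

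Of 13855 genes tested in HPC, 682 were higher and 594 lower in hom than in WT. The largest rises also took in Mgam (log2 2.29 ± 0.19), Rgs8 (1.81 ± 0.19), the sphingomyelin synthase Sgms2 (1.71 ± 0.20) and the secretory kinase Fam20c (1.65 ± 0.31). The largest falls also took in the luteinising hormone receptor Lhcgr (-2.22 ± 0.23), the Src-family kinase Yes1 (-2.22 ± 0.24), 14.5% of whose exons overlap Gm10461, and the adhesion molecule Dscam (-2.17 ± 0.21). Slamf1, whose product CD150 was used to sort these cells, fell to 62.5% of WT (edgeR adjusted p = 0.0179), while Procr and Kit did not pass (log2 0.07 ± 0.18 and 0.20 ± 0.07).

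Among lists long enough for a set test, granule and monocyte markers formed the strongest shift in HPC hom. Of 18 neutrophil granule genes, 15 rose, none fell and 3 did not pass (16 rose adjusted over the list alone), among them the granule proteins Ctsg (log2 0.77 ± 0.06), Mpo (0.64 ± 0.08, from 1214 to 1898 CPM) and Prtn3 (0.78 ± 0.09). Of 16 monocyte and macrophage genes, 13 rose, none fell and 3 did not pass (13 rose adjusted over the list alone), among them Ly6c2, F13a1, Adgre1, which encodes the F4/80 antigen (1.33 ± 0.09), and the lysozyme gene Lyz2 (0.98 ± 0.07). Both calls held with an estimated correlation (camera adjusted p = 1.9e-14 for each; adjusted p = 0.0245 for each with an estimated correlation). All 4 eosinophil genes also rose, including Prg2 (1.40 ± 0.12) and Il5ra (1.49 ± 0.20), a list too short for a set test (4 rose adjusted over the list alone). Of 14 mast cell and basophil genes, 7 rose, 2 fell and 5 did not pass (8 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.00574; adjusted p = 0.155 with an estimated correlation), with Hdc, the histamine-forming enzyme, higher (1.22 ± 0.09) and the granzyme gene Gzmb lower (-1.17 ± 0.08).

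**Figure D2:**
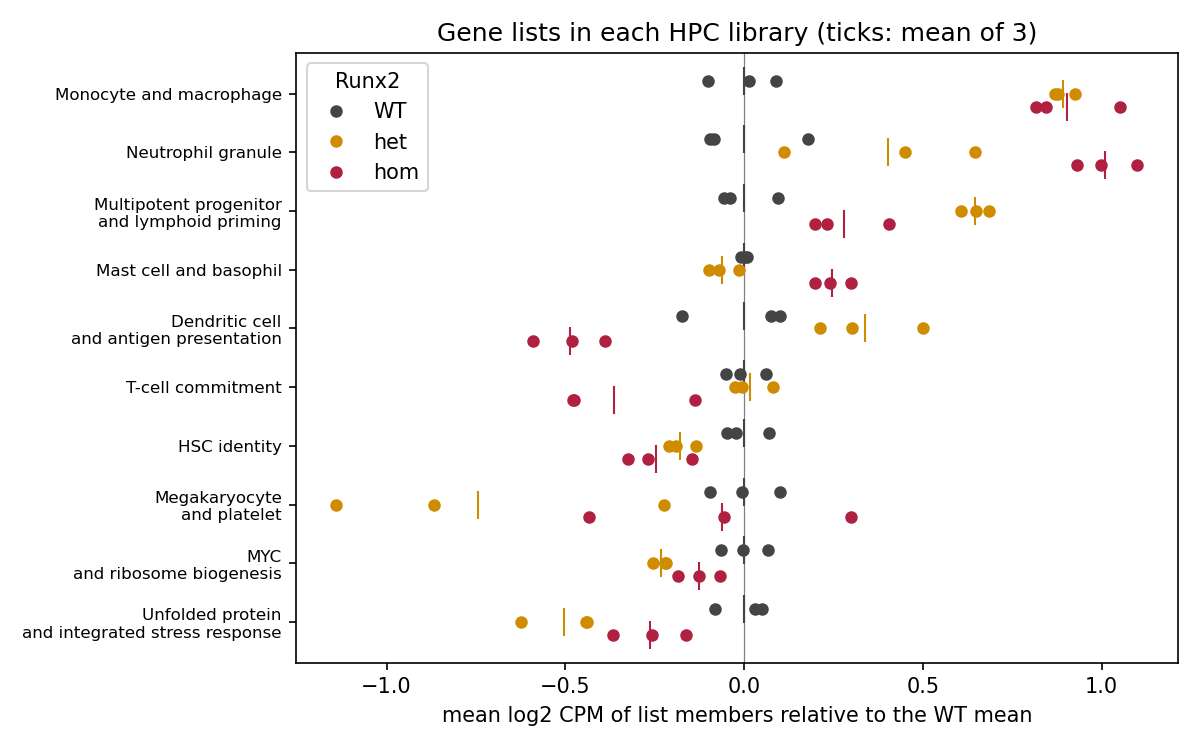
Mean log2 CPM of the members of 10 fixed gene lists in each HPC library, relative to the WT mean (horizontal axis), with 1 point per library, colours for the genotype and ticks for the mean of 3 libraries. Monocyte genes lie at 0.87 to 0.93 in het and 0.82 to 1.05 in hom, and dendritic cell genes at 0.21 to 0.50 in het and -0.59 to -0.39 in hom.

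In HPC hom, a minority of T-cell commitment and HSC identity genes fell. Of 18 T-cell commitment genes, 6 fell, 1 rose and 11 did not pass (6 fell and 1 rose adjusted over the list alone). Thy1 fell by 1.80 ± 0.15 on the log2 scale, Tox by 1.53 ± 0.13 and Tcf7 by 1.41 ± 0.19. The costimulatory receptor Cd28 rose by 0.62 ± 0.09. The list as a whole did not pass with camera (adjusted p = 0.0835), though it did with fry, a rotation test (adjusted p = 0.0264). Of 29 HSC identity genes, 12 fell, 2 rose and 15 did not pass (12 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.46 with an estimated correlation). The endothelial and stem-cell kinase Tie1 fell by 0.64 ± 0.06 and Mecom by 0.51 ± 0.07, whereas Hlf, a transcription factor of stem cells, rose by 0.48 ± 0.07. Of 16 dendritic cell and antigen-presentation genes, 7 fell, 1 rose and 8 did not pass (7 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.126), with Cd83 at -0.86 ± 0.20 and Itgax at -0.69 ± 0.17.

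In HPC hom the lymphoid-priming and adhesion lists were called higher and the stress-response list lower, with most members of each not past the test and no call held with an estimated correlation. Of 19 progenitor and lymphoid-priming genes, 7 rose, 2 fell and 10 did not pass (9 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0052; adjusted p = 0.615 with an estimated correlation). Dntt, the terminal transferase of lymphocyte precursors, rose by 1.48 ± 0.12 and Flt3 by 0.49 ± 0.08. Of 26 integrin and adhesion genes, 9 rose, 3 fell and 14 did not pass (12 rose and 3 fell adjusted over the list alone), with Itgam at 0.75 ± 0.07 and Esam at -1.05 ± 0.18 (camera adjusted p = 0.00574; adjusted p = 0.615 with an estimated correlation and 0.0574 without WT replicate 1). Of 20 unfolded-protein and integrated stress response genes, 7 fell, none rose and 13 did not pass (9 fell adjusted over the list alone), including Sesn2 at -0.52 ± 0.08 and Xbp1 at -0.26 ± 0.06 (camera adjusted p = 0.00208; adjusted p = 0.615 with an estimated correlation and 0.0619 with fry). In the MYC and ribosome biogenesis list only Mycn fell (-0.77 ± 0.05) and 21 of 22 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.0052; adjusted p = 0.615 with an estimated correlation and 0.0652 without WT replicate 1). None of 25 G2 and mitosis genes passed in HPC hom (0 also adjusted over the list alone; camera adjusted p = 0.793). Across all 3 genotypes 2734 HPC genes differed. The count of 1276 genes for hom against WT stayed within 1.5 times under every alternative tried.

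Heterozygous HPC, with Runx2 at 82.7% of WT, differed from WT in more genes than hom HPC did. The lymphoid-priming and monocyte lists were called higher and the G2 and S phase lists lower, but none with an estimated correlation (adjusted p = 0.186, 0.0545, 0.373 and 0.646). Dntt rose from 6.24 ± 1.33 to 28.1 ± 0.93 CPM (SD, n = 3; log2 2.17 ± 0.12, edgeR adjusted p = 4.75e-09), Flt3 rose from 175 to 351 CPM (log2 1.00 ± 0.08), and Wfdc17 rose by log2 1.70 ± 0.09. Ly6c2 rose by 2.57 ± 0.16 and Acot1, an acyl-CoA thioesterase, by 1.66 ± 0.18. The amino acid transporter Slc7a3 fell by 2.40 ± 0.25, Xlr3b by 2.10 ± 0.27 and the stress-response gene Nupr1 by 1.97 ± 0.24. Slamf1 fell to 33.5% of WT (adjusted p = 1.62e-05) and Kit rose to 130% (adjusted p = 0.000997), both markers of the sort, while Procr did not pass (log2 0.30 ± 0.18). Of 13855 genes, 1268 were higher and 968 lower in het than in WT, and the count stayed within 1.5 times under every alternative tried.

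In the lists, 12 of 19 lymphoid-priming genes rose in het HPC, none fell and 7 did not pass (15 rose adjusted over the list alone; camera adjusted p = 1.56e-09). Of 16 monocyte genes 12 rose, none fell and 4 did not pass (13 rose adjusted over the list alone; camera adjusted p = 9.82e-13). Irf8, a transcription factor of monocytes and dendritic cells, rose by log2 1.10 ± 0.08 and the integrin Itgam by 1.11 ± 0.07. Among proliferation lists, 11 of 25 G2 and mitosis genes and 7 of 24 S phase genes fell, none rose and 14 and 17 did not pass (17 and 10 fell adjusted over the list alone; camera adjusted p = 6.41e-06 and 0.000146). Of 22 MYC and ribosome biogenesis genes, 12 fell, none rose and 10 did not pass (18 fell adjusted over the list alone; camera adjusted p = 4.31e-08), with the nucleolar proteins Nop58 and Nop56 at -0.42 ± 0.06 and -0.33 ± 0.06. Of 20 stress-response genes, 9 fell, none rose and 11 did not pass (11 fell adjusted over the list alone; camera adjusted p = 1.15e-05), with the serine synthesis enzyme Psat1 at -0.92 ± 0.07 and Chac1 at -1.57 ± 0.13. Of 24 megakaryocyte genes, 7 fell, 1 rose and 16 did not pass (7 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.000309), including the platelet genes Gp5 (-1.51 ± 0.19) and Gp9 (-1.01 ± 0.19). None of these calls held with an estimated correlation. The adjusted p was then 0.186 for MYC, 0.354 for stress-response and 0.532 for megakaryocyte genes. With fry the S phase and megakaryocyte calls were also lost (adjusted p = 0.153 and 0.0725). Of 18 T-cell commitment genes, 4 rose, 4 fell and 10 did not pass (4 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.88), with Thy1 (-1.38 ± 0.14) and Lck (-0.84 ± 0.13) lower and Cd28 higher (0.90 ± 0.09).

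Hom and het HPC also differed from each other when compared directly. Pgr, the progesterone receptor, stood at 5.90 ± 1.71 CPM in hom against 36.0 ± 8.66 in het (SD, n = 3; log2 -2.61 ± 0.22, edgeR adjusted p = 9.24e-05). H2-Eb1 and H2-Aa were lower by 2.56 and 2.49, and Nr4a3 had a change of -2.18 ± 0.22. S100a9 was higher in hom by log2 1.66 ± 0.23, the folate enzyme Aldh1l2 by 1.47 ± 0.30 (a call lost in 5 of the 6 fits that left out 1 library) and Mgam by 1.47 ± 0.18. Levels in WT were 15.4 ± 1.78 CPM for Pgr, 3.55 ± 0.57 for Nr4a3, 27.07 ± 8.52 for Aldh1l2 and 2.37 ± 0.42 for Mgam, against 36.0, 6.58, 8.31 and 4.22 CPM in het, so het differed from WT as well. Of 16 dendritic cell genes, 10 were lower in hom, none higher and 6 did not pass (12 lower adjusted over the list alone; camera adjusted p = 4.66e-07; adjusted p = 0.119 with an estimated correlation). Of 18 neutrophil granule genes, 10 were higher, none lower and 8 did not pass (11 higher adjusted over the list alone; camera adjusted p = 1.02e-05; adjusted p = 0.119 with an estimated correlation). Both lists had been called higher in het than in WT, with 6 of 16 and 8 of 18 genes up and none down (camera adjusted p = 0.00225 and 0.000106; adjusted p = 0.354 and 0.186 with an estimated correlation). Of 19 erythroid genes 8 were higher, 1 lower and 10 did not pass (9 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00128; adjusted p = 0.468 with an estimated correlation and 0.0804 with fry). Of 18 T-cell commitment genes, Tox, Tcf7 and Cd7 were lower in hom, Lat was higher and 14 did not pass (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00418; adjusted p = 0.257 with an estimated correlation). Slamf1 was 187% of the het level (adjusted p = 0.00819), and Procr and Kit did not pass (log2 -0.23 ± 0.18 and -0.17 ± 0.07). In all, 503 genes were higher and 800 lower, and the total of 1303 was 701 without het replicate 2 and 797 without hom replicate 3.

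Het and hom effects in HPC went mostly the same way. Of the calls against WT, 466 genes were higher and 259, Runx2 included, lower in both het and hom, against 62.4 and 41.5 for independent lists. Only 16 and 1 went opposite ways. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.57 and a covariance of 0.0895, where 20 simulated pairs of unchanged groups against the same WT libraries gave a mean r of 0.48 and a covariance of 0.0199. With het and hom each taken against WT libraries of its own, 1 against 2, the covariance was 0.0676 to 0.0812 and 228 to 395 genes were called the same way in both, against 3 to 14 opposite. A difference common to all 3 WT libraries would remain in these values. Of 1275 genes called in hom HPC besides Runx2, the het value lay between WT and hom for 722, beyond the hom value for 417 and on the other side of WT for 136. These genes were chosen on the hom call and both changes share the WT libraries, so the counts do not measure an effect of dose. The HSC correlation was r = 0.55 (simulated 0.50) and the covariance 0.0851 (simulated 0.0359), and with separate WT libraries r was 0.16 to 0.26, the covariance 0.037 to 0.0587 and 0 to 2 genes besides Runx2 were called the same way in both.

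A common set of genes moved in hom cells of both populations. Il18r1, Tox, Tcf7, Thy1, H2-Aa, H2-Eb1, Ccr7, Ccl22 and Serpinh1 fell in both, and Tlr7, Ifi209 and Rgs8 rose in both. H2-Aa and H2-Eb1 lie within 20 Mb of Runx2, so an effect of the segment around Runx2 on them cannot be excluded. Among 13493 genes tested in both cell types, 47 were higher in both against 7.94 by chance (Fisher's exact test, one-sided, p = 6.86e-24) and 45 lower in both against 4.97 (p = 9.31e-32). Opposite calls numbered 2 (higher in HSC and lower in HPC, against 7.65 by chance) and 5 (the reverse, against 5.16). The latter included Lpl, which fell by 1.99 in HSC and rose by 1.51 ± 0.18 in HPC. Of the 291 genes called in HSC and measured in HPC, besides Runx2, 71.5% changed in the same direction there, called or not. Across all genes there was little agreement in direction, with the same sign for 50% and a Spearman rho of 0.134 (Pearson r = 0.38). The 2 cell types have separate WT libraries, but a difference of WT from knockout libraries that is common to both and unrelated to Runx2 would remain in this overlap. Sva and Gm32920, among the shared genes, had 0 counts in every WT library of both cell types. The count of 92 shared genes was 193 with DESeq2 and 21 at an adjusted p under 0.01.

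**Figure D3:**
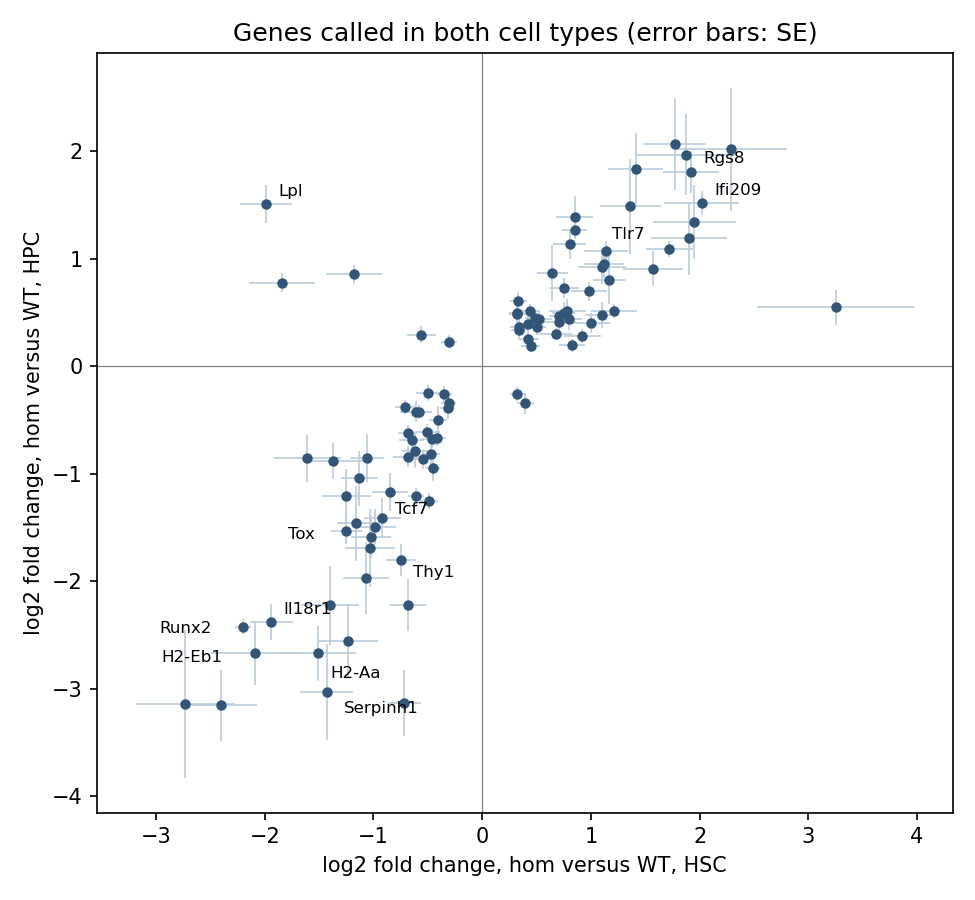
Log2 fold change of hom against WT in HSC (horizontal axis) and HPC (vertical axis) for the genes called in both cell types except Sva and Gm32920 (0 counts in WT), with error bars for the SE. Most lie in the lower left, such as Il18r1 at -1.94 and -2.38, or the upper right, such as Tlr7 at 1.14 and 1.07, and Lpl lies in the upper left.

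The effect of hom on monocyte genes differed between HSC and HPC by a test of the difference itself. Relative to WT the list mean was -0.55 to -0.07 in the 3 hom HSC libraries, where the list did not pass, and 0.82 to 1.05 in the hom HPC libraries. In 1 fit of all 18 libraries, 431 of 15431 genes differed in their hom effect, 164 with a higher and 267 with a lower value in HSC. Of 16 monocyte and macrophage genes, 6 had a lower effect in HSC, none a higher one and 10 did not pass (12 lower adjusted over the list alone), and the call held with an estimated correlation (camera adjusted p = 1.66e-11; adjusted p = 0.00366 with an estimated correlation). Ccr2 went from 3.39 ± 0.81 to 0.93 ± 0.21 CPM in HSC and from 38.5 ± 3.42 to 66.0 ± 2.12 CPM in HPC (SD, n = 3; difference -2.65 ± 0.24, edgeR adjusted p = 9.73e-07). Lyz2 stood at 146 ± 5.48 CPM in WT and 140 ± 7.04 in hom HSC, and at 185 ± 8.48 and 363 ± 34.1 CPM in HPC (SD, n = 3; difference -1.04 ± 0.10, edgeR adjusted p = 1.77e-06). Of 25 interferon genes, Irf7, Oas2, Oas3 and Usp18 had a higher effect in HSC, none a lower one and 21 did not pass (12 higher adjusted over the list alone; camera adjusted p = 3.35e-06; adjusted p = 0.692 with an estimated correlation and 0.201 with fry). Of 25 G2 and mitosis genes, Ccnb1, Nusap1, Ccna2 and Anln had a lower effect in HSC, none a higher one and 21 did not pass (12 lower adjusted over the list alone; camera adjusted p = 2.95e-07; adjusted p = 0.405 with an estimated correlation). Procr, Slamf1 and Kit did not differ in their hom effect by this test (differences of 0.06 ± 0.28, 0.52 ± 0.22 and -0.08 ± 0.10). Cell type and donor sex could not be told apart in this contrast. The count was 851 with DESeq2 and 738 without a filter. It was 220, 194 or 286 without HSC WT replicate 1, 2 or 3, 167 or 941 without HSC hom replicate 2 or 3, 149 or 151 without HPC WT replicate 2 or 3, and 257 or 155 without HPC hom replicate 1 or 3.

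The genes with the largest differences in hom effect included Ly6c2, Prg2, Ifitm6 and Fcer1a, with a lower effect in HSC, and Cox6a2, Dpysl5, Apol10b and Gpr174, with a higher one. Ly6c2 stood at 0.29 ± 0.15 and 0.07 ± 0.12 CPM in WT and hom HSC and at 1.74 ± 0.30 and 16.2 ± 1.21 CPM in WT and hom HPC (SD, n = 3). Prg2, a granule protein of eosinophils, went from 12.3 ± 1.37 to 32.2 ± 4.93 CPM in HPC and stood at 0.37 ± 0.13 and 0.05 ± 0.05 CPM in WT and hom HSC. Dpysl5 went from 1.65 ± 0.35 to 0.07 ± 0.06 CPM in HPC and from 11.4 ± 3.76 to 7.60 ± 3.59 in HSC. A level of 3 counts, the floor used here, equals 0.111 to 0.18 CPM, so that the HSC side of Ly6c2 and Prg2 was near it and the size of their difference was not well measured. Fcer1a had 0 counts in all 3 hom HSC libraries and 0.27 ± 0.13 CPM in WT HSC. In HPC this gene fell as well, from 14.8 ± 3.29 to 8.67 ± 1.85 CPM (log2 -0.77, edgeR adjusted p = 0.0214). Cox6a2 stood at 0.01 ± 0.02 and 0.39 ± 0.12 CPM in WT and hom HSC, and its change in HPC did not pass (log2 -0.57, edgeR adjusted p = 0.467). The HSC side of Fcer1a and Cox6a2 was thus near the floor too.

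WT HSC and WT HPC differed in most of the genes tested. Procr (CD201) was 810% and Slamf1 (CD150) 177% of the HPC level in HSC; both define the gates and are no finding. Of 29 HSC identity genes, 22 were higher in HSC, 3 lower and 4 did not pass (23 higher and 3 lower adjusted over the list alone; camera adjusted p = 1.15e-06; adjusted p = 0.298 with an estimated correlation), with Esam at log2 2.73 ± 0.15. The myeloid lists were lower in HSC. Of 18 neutrophil granule genes 13 were lower, 2 higher and 3 did not pass (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 8.35e-06; adjusted p = 0.064 with an estimated correlation). Of 16 monocyte genes 12 were lower, 1 higher and 3 did not pass (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.08e-06, held with an estimated correlation at 0.0399). Mpo stood at 20.7 ± 7.05 CPM in HSC and 1304 ± 34.3 in HPC (SD, n = 3). Il1rl1, a receptor of mast cells and innate lymphoid cells, stood at 0.20 ± 0.18 and 36.1 ± 2.12 CPM. Of 25 interferon genes, 21 were lower in HSC, 1 higher and 3 did not pass (21 lower and 2 higher adjusted over the list alone; camera adjusted p = 1.65e-06; adjusted p = 0.384 with an estimated correlation). Runx2 did not pass between the populations (log2 -0.04 ± 0.06), nor did Kit (-0.02 ± 0.07), while Runx1 was lower in HSC (-0.49 ± 0.06, edgeR adjusted p = 1.15e-06). Of 15431 genes, 4274 were higher and 4195 lower in HSC. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d and the X-linked Xist also differed, and cell type and sex could not be told apart here. Ly6a, which encodes the sort marker Sca1, had 0 counts in all 18 libraries and was not measured by these counts.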

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

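The explanations by shared WT libraries, by a WT group apart as a whole, by donor sex and by a smaller share of the main cell type were chosen for testing after the result was seen, and all other tests were written before.

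A difference between groups, tested by the interaction term of the joint fit, set 431 genes apart by their hom effect in HSC and HPC. On the log2 scale the effect in HSC minus that in HPC was 4.86 for Cox6a2, 3.84 for Dpysl5, 3.21 for Apol10b, 2.67 for Gpr174 and 1.51 for Yes1. It was -1.28 for Serpinf1, -1.77 for F13a1, -2.06 for Mgam, -2.27 for Fam20c, -3.53 for Lpl, -4.03 for Ifitm6, -4.25 for Prg2, -4.79 for Fcer1a and -5.26 for Ly6c2. The values of Cox6a2, Gpr174, Ifitm6, Prg2, Fcer1a and Ly6c2 in HSC, and of Dpysl5 and Apol10b in HPC, rest on levels near the count floor. Fcer1a had 0 counts in hom HSC, so its value is a fitted one that depends on the prior count and is no bound. By the same contrast the list means were 0.488 for megakaryocyte and platelet, -0.977 for neutrophil granule, -1.42 for monocyte and macrophage, -0.241 for G2 and mitosis, 0.331 for interferon response and -0.653 for immediate early and handling-stress genes. The neutrophil mean takes in S100a8, S100a9 and Fcnb, which had 0 counts in at least 1 HSC group, and is no bound. The monocyte mean takes in Ly6c2, at 0.07 CPM in hom HSC, so its size is not well measured either. In the fit of HSC alone, 13 monocyte genes passed the count filter, with a mean hom effect of -0.263. Only the monocyte call held with an estimated correlation (adjusted p = 0.00366, against 0.769 for megakaryocyte, 0.105 for neutrophil, 0.405 for G2 and mitosis, 0.692 for interferon and 0.769 for handling-stress genes). Megakaryocyte, interferon and handling-stress genes were also lost with fry (adjusted p = 0.335, 0.201 and 0.231). Without HSC WT replicate 3, HSC hom replicate 3 or HPC hom replicate 1 the megakaryocyte list had an adjusted p of 0.0527, 0.0675 or 0.232, and without HSC WT replicate 2 or HPC hom replicate 2 the handling-stress list 0.142 or 0.059.

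The different hom effect in HSC and HPC could reflect cell type or donor sex, since every HSC library was male in type and every HPC library female. X- or Y-linked genes, among them Gpr174, made up 5.57% of the 431 genes and 3.43% of those tested. Fisher's exact test, which treats genes as independent, gave p = 0.0213 for this excess. No group holds both sexes, so cell type and sex cannot be told apart here. Genes near the count floor are not the main source: 6.96% of the 431 genes had a mean under 1 CPM throughout one cell type, far from a majority. Among 100 splits of the libraries, the real one included, 2 gave as many genes, the highest other being 1138 in the split that exchanges hom and WT in HPC and so adds the 2 effects.

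In HPC, het and hom both differ from WT and het does not lie between them for many genes. The sharing of WT libraries is argued against as the whole source of the shared part. With het and hom each set against WT libraries of its own (6 ways), the covariance of their changes was 0.0676 to 0.0812. It was 0.0895 with WT libraries shared, and 0 is expected for independent unchanged libraries. The spread around 0 was not simulated for these splits, and genes of a library move together. HSC, with few het calls, gave 0.037 to 0.0587, so chance between libraries is not excluded. A WT group apart as a whole would leave hom and het alike, against 1303 genes called between them. Still, such a difference cannot be told apart from a genotype effect for the 725 genes that both moved the same way, since the series holds no other WT HPC libraries. A few genes, chosen after their values were seen, go with such a difference. Sva and Gm32920 had 0 counts in every WT library of both cell types and were present in het and hom. Commd10 stood at 21.2 CPM in WT, 52.2 in het and 50.5 in hom HPC. A passenger segment around Runx2 is argued against as the source of most HPC calls. The called share within 20 Mb was 19% against 19.8% elsewhere (ratio 0.964 in HPC, 1.21 in HSC). Such a share cannot exclude an effect of the segment on a few genes, and H2-Aa, H2-Eb1 and H2-DMa lie within this window. Genes that vary between single cultures or animals remain a possible source: genes most variable within HSC groups were called in HPC 2.17 times as often as the others (41.9% against 19.3%; stratified odds ratio 3.05, 2.60 to 3.59). A dose effect of Runx2 and differences between cultures or animals may both contribute, and the labels give no replicate structure that would set them apart.

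Neutrophil granule and monocyte genes are higher in HPC hom than in WT, which may reflect expression within cells or more myeloid cells. A smaller share of the main cell type would raise the other lineages alike. Their means ran from 0.352 (erythroid) and 0.246 (mast cell) through -0.0223 (megakaryocyte, SD 0.303) to -0.475 (dendritic, SD 1.07), beside 1.05 for neutrophil genes. The megakaryocyte and dendritic means thus did not rise with them, although the 4 eosinophil genes, too few for a list test, all rose. Each gap had a permutation adjusted p of at most 0.00338. The neutrophil list was chosen for its rise and the permutation treats genes as independent, so these p-values decide nothing. Gene length is argued against as the source. The median of the 34 members was 0.808 after the joint trend on gene length and expression was subtracted and 0.796 before. The spread of their changes was 6.37 times the median standard error, where a value over 2 had been set in advance against a larger share of myeloid cells. That prediction was wrong: WT levels of the members ran from 0.121 to 1210 CPM, so more myeloid cells need not raise all by a common factor, and the explanation stays open.

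Splits of the 9 libraries into genotypes called fewer genes than the real one: in 100 splits the real one alone (1 of them) reached 150 in HSC, with 34 the highest other, and 1 reached 2734 in HPC, with 662 the highest other. For comparisons of 3 with 3 there are only 10 splits, too few for a test. Their real counts and highest others were 300 and 1 for hom against WT, 5 and 1 for het against WT and 2 and 0 for hom against het in HSC, 1276 and 0, 2236 and 1, and 1303 and 0 in HPC, and 8469 and 0 for WT HSC against WT HPC.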

How the results depend on the processing

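The run without X- and Y-linked genes was chosen after the result was seen, and all other alternatives before. Of 260 alternative values of the main results, 200 were the same, 37 weaker, 23 stronger and none reversed, and of 3585 others (named genes and lists) 3129, 375, 81 and none. A count was the same within 1.5 times, and a gene or list with the same direction and call. By this rule counts, lists without a call and lists tested with an estimated correlation could not be reversed. The absence of reversals therefore speaks only for single genes and for called lists in the other settings. The cause was not tested, except that left-out libraries and 2-group fits hold fewer samples. Gene counts in HSC depended on the method and on which library was left out. For hom against WT (300) they were 810 with DESeq2, 898 without a filter, 155 with 2 groups and 48 to 638 with 1 library left out. For het against WT (5) they were 216, 399, 299 and 2 to 7, and for hom against het (2) 174, 511, 1 and 1 to 408, with 11 by limma-voom. Any difference in HSC (150) gave 826 with DESeq2, 1246 without a filter and 25 to 786. The interaction (431) gave 851, 738 and 149 to 941, and 405 without X- and Y-linked genes. HPC counts stayed within 1.5 times, except hom against het (1303), which ran from 701 to 1179 with 1 library left out. Runx2 in het HSC ran from -0.55 to -0.49, with the call lost in 5 of 6 fits. List calls went from 84 to 5 with an estimated correlation. Shared hom calls (92) were 193 with DESeq2 and 21 at an adjusted p under 0.01, and shared HSC het and hom calls (5) 103 with DESeq2.

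The labels do not say whether the replicate numbers pair the libraries, and correlations did not settle it. Same-numbered libraries correlated at -0.127 to 0.14 in HSC and -0.114 to 0.228 in HPC, and differently numbered ones at -0.177 to 0.202 and -0.274 to 0.272. Same-numbered WT and hom libraries all correlated positively (0.0301 to 0.14 in HSC, 0.0483 to 0.228 in HPC), while same-numbered pairs with het went both ways. With a replicate block the counts were 189 for hom against WT and 86 for any difference in HSC, and 713 for the interaction, and the block moved no other count by over 1.5 times. Depth limits genes near 0.111 to 0.18 CPM.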

Other observations

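The genes in this part were chosen after their values were seen.

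A few genes separated WT from both knockout genotypes in both cell types without regard to dose. Commd10 (chromosome 18), whose product takes part in endosomal sorting, stood at 27.2 CPM in WT, 52.1 in het and 49.5 in hom HSC, and at 21.2, 52.2 and 50.5 CPM in HPC. Sva (chromosome 6) had 0 counts in all 6 WT libraries and 2.33 and 2.2 CPM in het and hom HSC and 1.63 and 1.36 CPM in het and hom HPC. Gm32920 (chromosome 1) had 0 counts in the same libraries and 1.64 and 1.42 CPM in HSC and 0.769 and 0.985 CPM in HPC.

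Gm3534 (chromosome 14) varied within HSC groups, from 0.171 to 7.09 CPM in WT and 0.0987 to 6.47 in het, and stood at 0.136 CPM in WT, 4.49 in het and 5.76 in hom HPC. Genes with libraries at least 10-fold apart within a group (highest at least 1 CPM) numbered 17 in HSC WT, 17 in HSC het, 58 in HSC hom, 0 in HPC WT, 10 in HPC het and 13 in HPC hom.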
